A study of Mus musculus with 12 samples.

How the data were processed

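Ventricle RNA from 6 Vps13c-cKO and 6 WT male mice, 7 weeks old, was compared. Per the labels' protocols, mRNA was captured with poly-T beads, fragmented and copied from random primers, and libraries were amplified by PCR without molecular identifiers, so counts are reads and not molecules. The deposited values are whole-number read counts per gene and mouse, per the file headers, with no normalization by the authors. The submitters' processing notes name fastp 0.22.0, HISAT2 2.1.0, HTSeq 0.9.1 and the genome build GRCm39. The annotation release and the strand setting are not given in the sources used here, and the protocol in the labels mentions no strand marking. Reads of genes that overlap on opposite strands therefore cannot be told apart. By the GENCODE M21 annotation, exons of Atp2a1 overlap Rabep2, those of Clcn1 overlap Fam131b, those of Pfkfb1 overlap Apex2, and those of Echs1 overlap Paox, on the opposite strand. The same holds for Ucp2 with Dnajb13, Ctsz with Nelfcd, Irf7 with Phrf1, Nr1d1 with Thra, Ndufs1 with Eef1b2, Lamp1 with Grtp1 and Ccnd1 with LTO1. Values of these genes are uncertain to that extent, and so are those of genes with close copies, among them Acot1, Cyp2b10, Ifit3, Ifit3b and the actin gene Acta1. Gene names, chromosomes and gene order came from GENCODE M21, an annotation of the build GRCm38. As that is another build than the one the counts were made on, no coordinates are given. Of 21959 gene IDs in the table, 21851 had a name there, and 99.4% of those are protein coding, so non-coding RNA is hardly covered.

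Group and replicate number were taken from the sample titles. The 12 columns were matched to mice by the names in the labels, and 0 columns of per-sample values went unused. Of the gene IDs, 4480 had 0 counts in all samples. The filter filterByExpr left 12384 genes for testing, which hold 99.9% of the counts. Replicates of one group differed by 3.11 to 5.62 chi-square units per gene over genes with 20 or more summed counts, where 2 counts of one library would differ by about 1, so no pair was treated as one library. Separate mice are expected to exceed that value.

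Genes were tested with the two-sided quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM factors and Benjamini-Hochberg adjustment over all tested genes, and a gene was called at an adjusted p under 0.05. Adjusted p-values of single genes come from this test throughout. Log2 fold changes are Vps13c-cKO minus WT and their errors are standard errors. CPM values use TMM-scaled library sizes and are given as mean ± SD over the mice of a group. The biological coefficient of variation was 0.0661. At these depths, a simulation on 12252 genes with the real means and library sizes recovered 70.2% of genes changed 1.25-fold, 90.0% at 1.5-fold, 98.0% at 2-fold and 100% at 4-fold, with 6 false calls among 182.

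Gene lists were fixed before the data were examined: 41 lists with 1132 members, of which 7 members had no ID in the table. The 39 lists with 5 or more tested genes were tested with camera of limma 3.58.1 on voom values, with a preset correlation of 0.01 between genes, and again with a correlation estimated for each list and with fry. List p-values are Benjamini-Hochberg adjusted over the 39 lists. A list counts as higher or lower by the camera test at an adjusted p under 0.05. Genes named in the text follow a rule fixed at the same time. It takes Vps13c, the 10 genes with the largest change in each direction among those called with a mean log2 CPM of 1 or more and no predicted or pseudogene name, and the 5 genes with the smallest p in each direction. It also takes up to 4 members with the smallest p of each list described, and Vps13a, Vps13b, Vps13d, Nppa, Nppb, Myh6, Myh7 and Acta1 whatever their values. Other genes were chosen after their values were seen, namely Tnnc2, Myh4, Myl1, Casq1 and further members of the lists of clock and fast-fibre genes. Chromosome shares were compared with two-sided Fisher's exact tests after the data were seen. These tests treat genes as independent, which they are not.

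Alternatives were DESeq2 size factors, upper-quartile factors, no filter, a minimum mean of 5 CPM, DESeq2 1.42.0, limma-voom with and without sample weights, robust empirical Bayes, the replicate number as a block, 1 surrogate variable (sva 3.50.0) and leaving out each sample. Leaving out chromosome 7 genes was added after the data were seen. No batch, litter or collection time is given in the sources used here, nor how the knockout was restricted to the heart. Whether the WT mice carried a driver of the knockout is not given either, so an effect of a driver cannot be set apart.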

Results

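Poly-A RNA from the heart ventricles of 12 male mice, each 7 weeks old and fed chow, was sequenced. In 6 mice Vps13c had been knocked out in the heart (Vps13c-cKO), and 6 mice were wild type (WT). Vps13c encodes a large bridge-like protein that carries lipids between organelle membranes at contact sites. The comparison asks how ventricular gene expression differs when this gene is depleted. Each sample is a separate mouse, per the labels. Libraries held 12484523 to 15562942 gene counts. The mean was 14130300 ± 867607 counts (SD, n = 6) in WT and 13400500 ± 681867 counts (SD, n = 6) in Vps13c-cKO (two-sided exact permutation p = 0.145). The share of counts on mitochondrially encoded genes was 30.1% ± 0.761 (SD) in WT and 31.2% ± 0.606 in Vps13c-cKO (n = 6 each, exact permutation p = 0.0238). Genes with at least 1 count numbered 14931 ± 53.1 (SD) in WT and 15259.7 ± 110 in Vps13c-cKO (n = 6 each, exact permutation p = 0.00216, the smallest p this design can give). In a principal component analysis the first component held 28.2% of the variance, and every Vps13c-cKO sample lay on the other side of it from every WT sample.

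Vps13c itself fell in every knockout ventricle. Its level was 61.9 ± 4.85 CPM (read counts normalised to library size; SD, n = 6) in WT and 18.2 ± 1.58 CPM (SD, n = 6) in Vps13c-cKO, which is 29.4% of the WT mean. The log2 fold change of Vps13c (ENSMUSG00000035284, chromosome 9) was -1.77 ± 0.06 (SE; edgeR quasi-likelihood test, adjusted p = 4.47e-14), and all 6 Vps13c-cKO samples lay below all 6 WT samples. Which exons were deleted is not given in the sources used here. The log2 fold changes of the paralogs were -0.05 ± 0.05 (SE) for Vps13a, 0.06 ± 0.06 for Vps13b and -0.02 ± 0.04 for Vps13d, with adjusted p = 0.664, 0.62 and 0.775. On the list of VPS13 family and related bridge-like lipid transfer proteins, which leaves out Vps13c, 0 of 9 tested genes passed the threshold (list adjusted p = 0.868).

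Most changed genes differed by less than 2-fold, and those beyond it were mostly higher. Of 12384 genes tested, 700 were higher and 631 lower in Vps13c-cKO at an adjusted p under 0.05. The median changed gene differed 1.21-fold, and 79 genes differed at least 2-fold, 73 of them higher and 6 lower. The steepest rise among named genes was that of Atp2a1, the calcium pump of fast skeletal muscle (chromosome 7, ENSMUSG00000030730), from 0.605 ± 0.259 CPM (SD, n = 6) to 33.0 ± 7.84 CPM (SD, n = 6), a log2 fold change of 5.78 ± 0.21 (SE, adjusted p = 4.49e-14). Cyp2b10, a cytochrome P450, rose by 4.22 ± 0.25 on the log2 scale and Tbx15, a T-box transcription factor, by 2.49 ± 0.28. Sytl2 rose by 2.02 ± 0.19 and the water channel gene Aqp8 by 1.98 ± 0.20. Like Atp2a1, the genes Cyp2b10, Sytl2 and Aqp8 lie on chromosome 7, where changed genes were concentrated. Ndnf, a secreted factor, rose from 7.83 ± 1.29 to 25.8 ± 4.07 CPM (SD, n = 6 each; log2 1.73 ± 0.11 SE). After Vps13c, the steepest fall among genes past the threshold was that of the nuclear receptor gene Nr4a3, from 16.9 ± 2.07 to 6.43 ± 3.14 CPM (SD, n = 6 each; log2 -1.40 ± 0.19 SE, adjusted p = 3.36e-05). The chloride channel gene Clcn1 fell by 1.21 ± 0.13 on the log2 scale, Grhl2 by 1.08 ± 0.24, the monoamine oxidase gene Maob by 0.89 ± 0.07, Cth by 0.86 ± 0.24, Pfkfb1 by 0.86 ± 0.12, the clock gene Arntl by 0.84 ± 0.18 and Clmn by 0.79 ± 0.15. Acot1, a thioesterase of fatty acyl-CoA, fell by 0.86 ± 0.13. Small but precise falls included Pdp2, a phosphatase that activates pyruvate dehydrogenase, from 51.7 ± 2.45 to 35.9 ± 2.70 CPM, and the muscle ribosomal protein gene Rpl3l, from 189 ± 6.58 to 138 ± 11.6 CPM (SD, n = 6 each; adjusted p = 6.64e-07 and 1.37e-06). The number of genes past 2-fold was 18 with a minimum mean of 5 CPM and 229 without a filter. It was 157 by DESeq2, which was also run without filterByExpr.

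**Figure D1:**
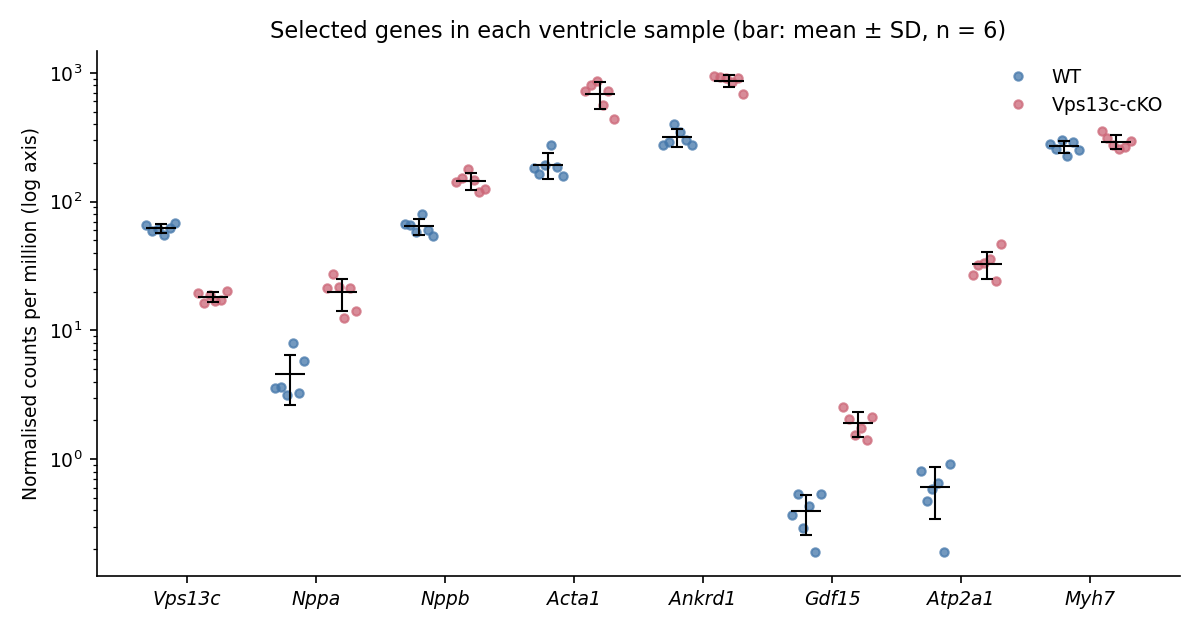
Normalised CPM (log axis) of 8 genes in each of the 6 WT and 6 Vps13c-cKO ventricles, with the mean ± SD of each group. All 6 Vps13c-cKO samples lie below the WT samples for Vps13c and above them for Nppa, Nppb, Acta1, Ankrd1, Gdf15 and Atp2a1, while the groups overlap for Myh7.

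Genes of cardiac stress rose together. Of 22 tested members of the list of cardiac stress and fetal genes, 15 were higher and 0 lower (16 higher and 0 lower adjusted over the list alone). Their median log2 fold change was 0.57, and 0.345 without the only chromosome 7 gene among them. Nppa, which encodes atrial natriuretic peptide, rose from 4.56 ± 1.93 to 19.7 ± 5.49 CPM (SD, n = 6 each), and Nppb, which encodes B-type natriuretic peptide, from 64.4 ± 9.02 to 144 ± 21.5 CPM. Skeletal alpha-actin (Acta1) rose from 194 ± 43.1 to 686 ± 159 CPM and the stress-induced titin-binding gene Ankrd1 from 315 ± 50.2 to 870 ± 98.7 CPM. Their log2 fold changes were 2.12 ± 0.20 (SE), 1.16 ± 0.09, 1.82 ± 0.14 and 1.47 ± 0.09. The 2 cardiac myosin heavy chain genes did not pass the threshold, with log2 fold changes of -0.06 ± 0.04 for Myh6 (adjusted p = 0.394) and 0.12 ± 0.07 for Myh7 (adjusted p = 0.304). The list's call held with the preset correlation of camera (adjusted p = 1.53e-18) and with an estimated correlation (adjusted p = 0.00139). Sarcomere genes went both ways, with 6 of 29 higher and 5 lower (6 and 6 adjusted over the list alone; list adjusted p = 0.673). Flnc rose by 0.35 ± 0.04 on the log2 scale, while Tnni3 fell by 0.22 ± 0.03, Tpm1 by 0.16 ± 0.03 and Fhl2 by 0.24 ± 0.04.

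Matrix genes and fibroblast markers rose in the same hearts. Of 41 tested genes on the list of extracellular matrix and fibrosis, 23 were higher and 0 lower (26 and 0 adjusted over the list alone; median log2 fold change 0.28). The matricellular gene Ccn2 rose from 50.5 ± 6.29 to 87.4 ± 10.8 CPM. The cartilage matrix gene Cilp rose from 9.24 ± 1.79 to 18.2 ± 1.61 CPM. The collagen I genes rose as well, Col1a1 from 71.1 ± 6.05 to 92.8 ± 5.38 CPM and Col1a2 from 111 ± 4.87 to 140 ± 9.47 CPM (SD, n = 6 each). Fibroblast markers were higher for 11 of 18 tested genes and lower for 0 (11 and 0 adjusted over the list alone; median 0.23), among them Fbln2 at 0.36 ± 0.05 (SE) and Lum at 0.33 ± 0.05. The matrix and fibroblast lists share 5 tested genes. The preset-correlation adjusted p was 4.96e-18 for the matrix list and 3.00e-10 for fibroblasts. With an estimated correlation the adjusted p was 0.0684 for the matrix list, which ends its call, and 0.0130 for fibroblasts. Macrophage markers were higher for 4 of 22 and lower for 0 (6 and 0 adjusted over the list alone; adjusted p = 0.00218, and adjusted p = 0.345 with an estimated correlation). These were the complement genes C1qa, C1qb and C1qc and the lysozyme gene Lyz2, at log2 fold changes of 0.27 to 0.37. Endothelial markers were lower for 2 of 19, Cldn5 and Cav1, and higher for 0 (2 lower adjusted over the list alone; adjusted p = 0.0270, and adjusted p = 0.365 with an estimated correlation). Smooth muscle and pericyte markers went both ways, with 2 of 17 higher and 3 lower (4 and 7 adjusted over the list alone; adjusted p = 0.261).

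On the skeletal muscle list, 5 genes of chromosome 7 rose from near the detection floor. Of 9 tested skeletal muscle genes, 7 were higher and 0 lower (7 and 0 adjusted over the list alone; median log2 fold change 2.77; adjusted p = 6.24e-15, and adjusted p = 0.00463 with an estimated correlation). Ryr1, the calcium release channel of skeletal muscle, rose from 0.335 ± 0.294 to 4.48 ± 0.775 CPM, the fast light chain gene Mylpf from 0.783 ± 0.126 to 7.32 ± 2.43 CPM, and the fast troponin genes Tnni2 and Tnnt3 from 0.757 ± 0.281 to 6.59 ± 1.05 CPM and from 0.720 ± 0.298 to 4.95 ± 1.09 CPM (SD, n = 6 each). Not every fast-fibre gene took part: Tnnc2 had 0 counts in all samples, Myh4 had 1 count in WT and 2 in Vps13c-cKO, Myh1, Myh2, Actn3 and Pvalb had at most 13 counts per group, and Myl1 was at 23.4 ± 5.98 and 21.1 ± 5.15 CPM. Atp2a1, Ryr1, Mylpf, Tnni2 and Tnnt3 all lie on chromosome 7. Without chromosome 7 genes, 3 tested genes were left on the list, of which 2, Acta1 and Casq1, were higher (median 1.59).

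Changed genes were concentrated on chromosome 7. Of 955 tested genes there, 177 changed (18.5%; 92 higher, 85 lower), against 10.1% of tested genes elsewhere, an odds ratio of 2.03 (95% interval 1.69 to 2.42; two-sided Fisher's exact test p = 7.30e-14, adjusted p = 1.46e-12 over 20 chromosomes). Of the 79 genes that changed at least 2-fold, 29 lay on chromosome 7 and all 29 were higher (odds ratio 7.12, 95% interval 4.32 to 11.5, adjusted p = 5.73e-12). No other chromosome had an adjusted p under 0.05 in either test, and on chromosome 9, which carries Vps13c, 10.9% of tested genes changed. The first 477 tested genes of chromosome 7 by order held 58 changed genes (12.2%) and the last 478 held 119 (24.9%). Against the other chromosomes the odds ratio was 1.23 for the first set (Fisher's exact p = 0.142). It was 2.95 for the last set (Fisher's exact p = 1.97e-19). The first set held 9 of the genes at least 2-fold higher and the last set 20. Arntl, Echs1, Uqcrc2, Cox6a2, Tnni3 and Hrc were among the chromosome 7 genes that fell. The median log2 fold change of all tested chromosome 7 genes was 0.0030. Without the chromosome 7 genes, a count added after the data were seen, 608 genes were higher, 546 lower and 50 changed at least 2-fold.

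**Figure D2:**
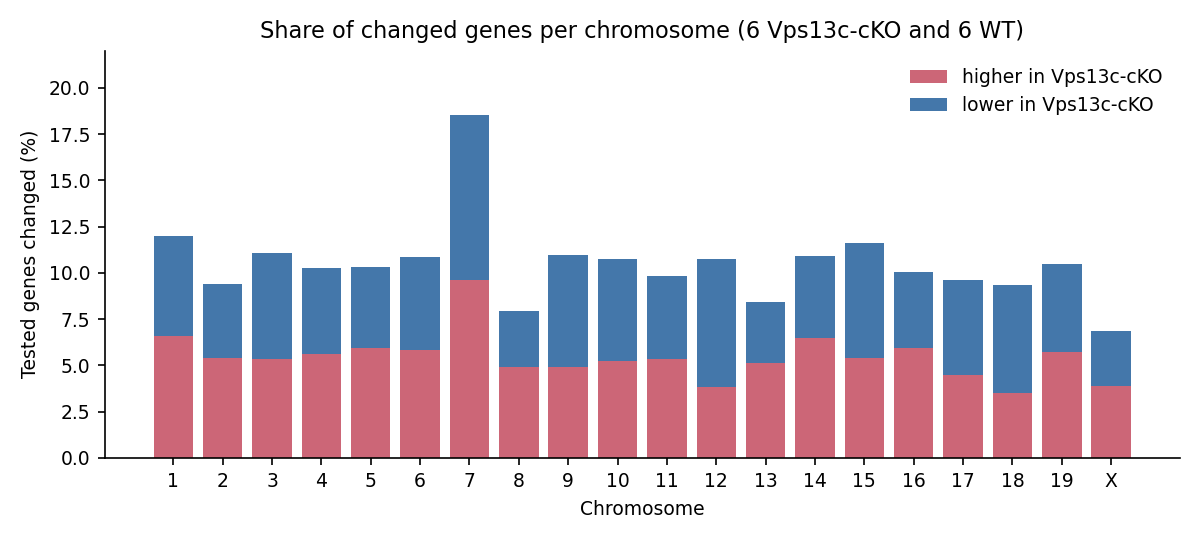
Percent of tested genes per chromosome that were higher or lower in Vps13c-cKO at an adjusted p under 0.05, stacked, from 6 Vps13c-cKO and 6 WT samples. Chromosome 7 reaches 18.5%, against 10.1% over the other chromosomes.

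**Figure D3:**
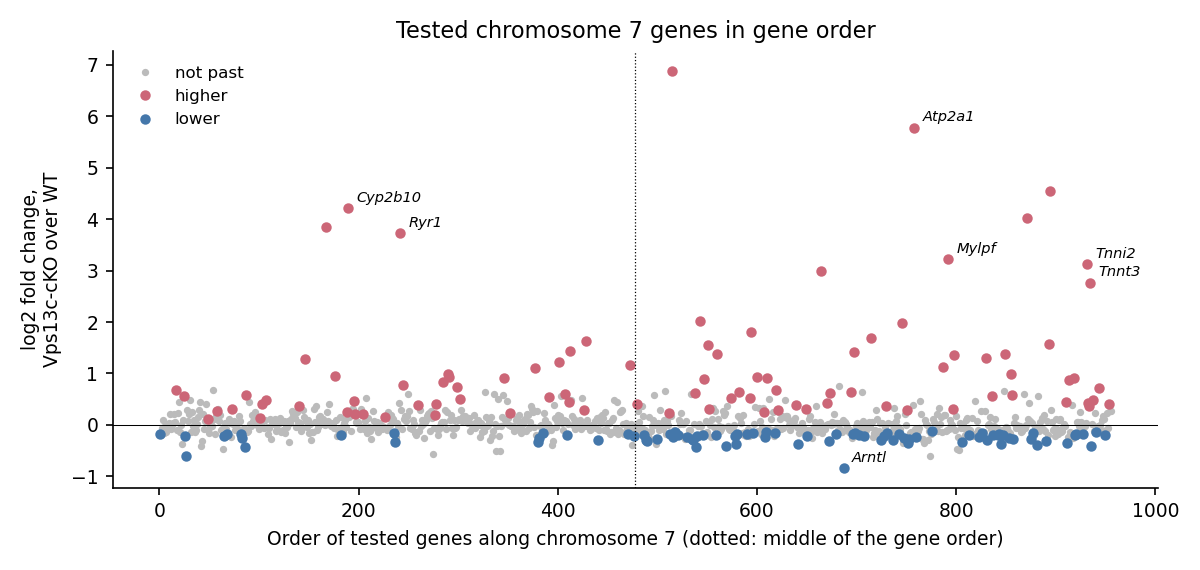
Log2 fold change of each tested chromosome 7 gene against its order along the chromosome, coloured by call. The last 478 genes hold 119 changed genes and the first 477 hold 58, and the steepest rises are near-silent genes in WT such as Atp2a1.

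Genes of fatty acid and branched-chain amino acid breakdown fell by small amounts. Of 41 tested genes of fatty acid uptake and oxidation, 20 were lower and 1 higher (26 and 1 adjusted over the list alone; median log2 fold change -0.16). The enoyl-CoA hydratase gene Echs1 fell from 294 ± 6.78 to 238 ± 7.32 CPM, lipoprotein lipase (Lpl) from 7976 ± 169 to 6910 ± 243 CPM, and the coactivator of mitochondrial genes Ppargc1a from 212 ± 28.8 to 154 ± 12.4 CPM (SD, n = 6 each). In contrast, the uncoupling protein gene Ucp2 rose from 47.2 ± 4.90 to 67.4 ± 7.45 CPM. Ucp2 lies on chromosome 7, and without chromosome 7 genes 19 of 37 genes on the list were lower and 0 higher. The adjusted p of the full list was 1.29e-14. With an estimated correlation the adjusted p was 0.119, which ends the call. Of 22 tested genes of branched-chain amino acid and ketone catabolism, 16 were lower and 1 higher (16 and 1 adjusted over the list alone; median -0.17; adjusted p = 3.03e-11, and adjusted p = 0.0110 with an estimated correlation). Bckdhb and Dbt, subunits of the branched-chain ketoacid dehydrogenase, fell by 0.37 ± 0.05 (SE) and 0.27 ± 0.04 on the log2 scale, its phosphatase gene Ppm1k by 0.30 ± 0.05 and Acadsb by 0.26 ± 0.04.

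Nuclear genes of oxidative phosphorylation were lower where they changed, and 0 mitochondrially encoded genes passed singly. For complexes II to V, 11 of 42 genes were lower and 0 higher (15 and 0 adjusted over the list alone; median log2 fold change -0.09; adjusted p = 2.07e-09, and adjusted p = 0.321 with an estimated correlation). Uqcrc2 and Cox6a2 fell by 0.29 ± 0.04 (SE) each, Sdha by 0.18 ± 0.03 and Atp5c1 by 0.17 ± 0.03. For complex I, 3 of 36 were lower and 0 higher (3 and 0 adjusted over the list alone; adjusted p = 0.0174, and adjusted p = 0.592 with an estimated correlation), namely Ndufab1, Ndufc2 and Ndufs1. Without chromosome 7 genes the adjusted p of complex I was 0.0791. Of 12 mitochondrially encoded genes, 0 passed the threshold singly (2 higher adjusted over the list alone; median 0.06; list adjusted p = 0.0279, and adjusted p = 0.365 with an estimated correlation). Glycolysis and glucose use went both ways, with 6 of 33 higher and 8 lower (9 and 10 adjusted over the list alone; adjusted p = 0.187). The hexokinase gene Hk2 fell by 0.26 ± 0.04, while Hk1 rose by 0.23 ± 0.04 and Pfkp by 0.28 ± 0.05.

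The lists of organelle contact sites and autophagy did not pass the threshold, while that of lysosomes did with the preset correlation. By fry, the contact site list was lower (adjusted p = 0.0483). Of 34 tested organelle contact site genes, 1 was higher (Gramd1b, 0.15 ± 0.04 SE) and 3 lower (Stard13, -0.39 ± 0.08; Osbpl1a, -0.20 ± 0.04; Ano10, -0.30 ± 0.08), with a list adjusted p of 0.366 (2 and 3 adjusted over the list alone). Of 61 lysosome genes, 8 were higher and 3 lower (9 and 3 adjusted over the list alone; median log2 fold change 0.05; adjusted p = 0.0345, and adjusted p = 0.217 with an estimated correlation). Ctsz was at 0.36 ± 0.08, Cd63 at 0.23 ± 0.06, Atp6v1d at 0.17 ± 0.04 and Lamp1 at 0.12 ± 0.03. Of 50 autophagy and mitophagy genes, 1 was higher, the cargo receptor gene Sqstm1 (0.20 ± 0.04), and 2 lower, Pink1 (-0.18 ± 0.05) and Atg10 (-0.25 ± 0.08), with a list adjusted p of 0.662 (1 and 1 adjusted over the list alone). Mitochondrial dynamics and protein import had 1 of 33 lower, Oma1, and 0 higher (0 and 0 adjusted over the list alone; adjusted p = 0.628). Lipid droplet and triglyceride genes went both ways, with 4 of 28 higher, among them Plin2 (0.26 ± 0.06), and 7 lower, among them Lpin1 (-0.27 ± 0.06) and Fitm2 (-0.19 ± 0.04; list adjusted p = 0.262, 4 and 8 adjusted over the list alone). Phospholipid and sphingolipid synthesis had 1 of 33 higher, Sgms1, and 0 lower (adjusted p = 0.868), and cholesterol synthesis 1 of 23, Insig1, and 0 lower (adjusted p = 0.743), each with 1 and 0 adjusted over the list alone. On the list of fatty acid synthesis and SREBP1 targets, 3 of 17 were higher and 0 lower (3 and 0 adjusted over the list alone; median 0.11; adjusted p = 0.00499, and adjusted p = 0.0450 with an estimated correlation). Thrsp rose from 19.01 ± 4.06 to 49.1 ± 5.38 CPM, Fasn from 18.5 ± 1.53 to 25.9 ± 2.84 CPM and Scd2 from 19.5 ± 2.30 to 25.2 ± 4.81 CPM (SD, n = 6 each). Thrsp lies on chromosome 7, and without chromosome 7 genes the estimated-correlation adjusted p of this list was 0.139.

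Stress response lists differed in direction. Of 23 tested p53 targets, 8 were higher and 0 lower (12 and 1 adjusted over the list alone; median log2 fold change 0.27; adjusted p = 1.60e-07, and adjusted p = 0.00463 with an estimated correlation). Phlda3 rose from 3.72 ± 0.715 to 10.1 ± 0.521 CPM (SD, n = 6 each), Eda2r by 0.83 ± 0.12 (SE) on the log2 scale, Aen by 0.40 ± 0.06 and Perp by 0.27 ± 0.04. Heat shock and cytosolic chaperone genes were higher for 8 of 21 and lower for 0 (9 and 0 adjusted over the list alone; median 0.07; adjusted p = 0.000278, and adjusted p = 0.129 with an estimated correlation). Hspb1 was at 0.23 ± 0.04 and Hspb7 at 0.19 ± 0.03. On the list of the integrated stress response, 6 of 35 were higher and 2 lower (9 and 4 adjusted over the list alone; median 0.09; adjusted p = 0.0202, and adjusted p = 0.129 with an estimated correlation). The secreted stress cytokine gene Gdf15 rose from 0.394 ± 0.138 to 1.91 ± 0.415 CPM (SD, n = 6 each), Chac1 by 0.64 ± 0.15 and Psat1 by 0.56 ± 0.13. Genes of the unfolded protein response of the endoplasmic reticulum were lower for 5 of 28 and higher for 0 (7 and 0 adjusted over the list alone; median -0.08; adjusted p = 0.000290, and adjusted p = 0.217 with an estimated correlation). Manf was at -0.42 ± 0.11, Hspa5 at -0.25 ± 0.07, Dnajb9 at -0.23 ± 0.05 and Canx at -0.17 ± 0.04. Oxidative stress defence genes were higher for 8 of 32 and lower for 1 (12 and 2 adjusted over the list alone; median 0.07; adjusted p = 0.0126, and adjusted p = 0.321 with an estimated correlation). Log2 fold changes were 0.45 ± 0.05 for Gpx3, 0.21 ± 0.04 for Gpx4 and -0.51 ± 0.07 for the iron exporter gene Slc40a1. Without chromosome 7 genes its adjusted p was 0.0729.

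The list of calcium handling and ion channels was lower with the preset correlation. Of 38 tested genes of calcium handling and ion channels, 9 were lower and 4 higher (13 and 6 adjusted over the list alone; median log2 fold change -0.09; adjusted p = 0.00218, and adjusted p = 0.119 with an estimated correlation). The potassium channel genes Kcnj3 and Kcnd2 fell from 107 ± 4.85 to 68.1 ± 7.95 CPM and from 48.4 ± 4.10 to 34.1 ± 1.66 CPM, and the sarcoplasmic reticulum calcium-binding gene Hrc from 1285 ± 45.5 to 1081 ± 48.1 CPM (SD, n = 6 each). The T-type calcium channel gene Cacna1h rose from 6.53 ± 1.02 to 10.97 ± 1.71 CPM (SD, n = 6 each). Atrial myocyte markers were higher for 3 of 9 (Nppa, Clu and Pam) and lower for 1 (Kcnj3), with 5 and 2 adjusted over the list alone (adjusted p = 0.0365, and adjusted p = 0.22 with an estimated correlation; without chromosome 7 genes, adjusted p = 0.106). In all, 15 lists were higher and 8 lower out of 39 tested with the preset correlation, and 5 and 1 with an estimated correlation. These were cardiac stress, skeletal muscle, p53 targets, fibroblasts and fatty acid synthesis, all higher, and, lower, branched-chain amino acid and ketone catabolism. Over 19 alternative settings with an estimated correlation, fatty acid synthesis passed in 10, p53 targets, fibroblasts and branched-chain amino acids in 18 each, and cardiac stress and skeletal muscle in 19. Other splits of the 12 samples gave a median of 9 lists past the same threshold with the preset correlation. Those with 3 mice of each group on either side gave at most 11. With the preset correlation some calls were lost over the same settings: the lysosome and mitochondrially encoded lists passed in 14, complex I in 16, endothelial cells in 15, atrial myocytes in 12, adipocytes in 11, and the integrated stress response, interferon-stimulated genes and cell cycle in 18 each. By fry, the lists of macrophages, complex I, endothelial cells, mitochondrially encoded genes, interferon-stimulated genes and cell cycle did not pass (adjusted p = 0.0828, 0.264, 0.108, 0.105, 0.117 and 0.108). Single-gene calls near the threshold were lost in some settings too. With robust empirical Bayes the adjusted p was 0.122 for Hspa5, 0.0691 for C1qa, 0.0535 for C1qb, 0.0534 for Scd2, 0.0656 for Myh11, 0.0736 for C3, 0.0882 for Ccnd2 and Per2, and 0.0768 for Nr1d1. Without a filter it was 0.0517 for Gramd1b. With each of the 12 samples left out in turn, Oma1 lost its call in 10 cases, Atg10 and Cidea in 8, Aldh1a2 in 7, Gramd1b in 6, Pink1 and Hspa5 in 5, Hspa4 in 4, Myh11 in 3 and Scd2 in 2. Cth lost its call without WT replicate 2 or 3 or Vps13c-cKO replicate 5 (adjusted p = 0.0578, 0.0589 and 0.0546).

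**Figure D4:**
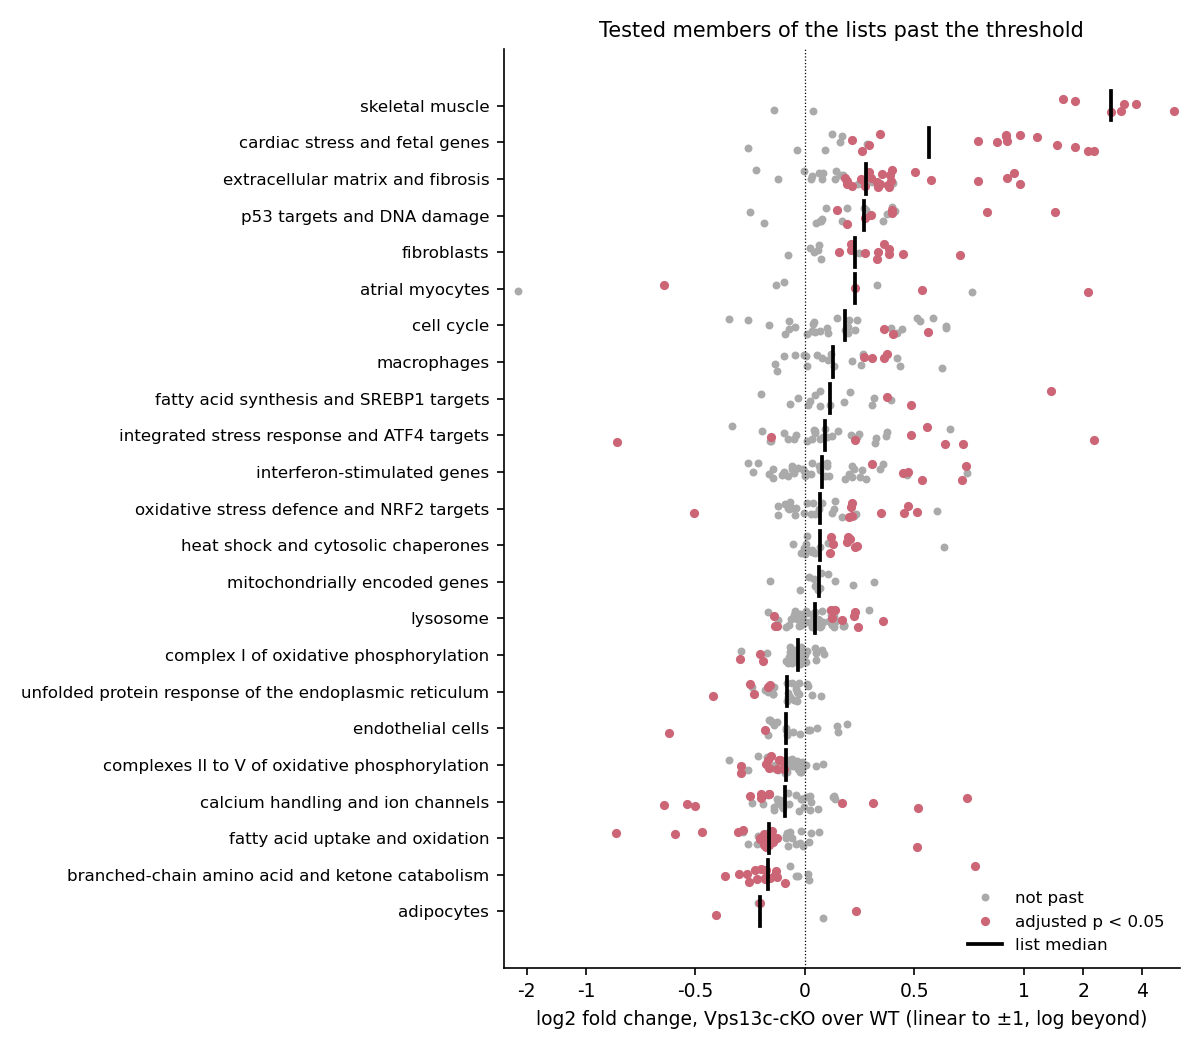
Log2 fold change (Vps13c-cKO over WT, linear to 1 and logarithmic beyond) of every tested member of the 23 lists past the threshold, each point a gene, with the list's median as a bar. Skeletal muscle and cardiac stress genes lie farthest to the right, with medians of 2.77 and 0.57, and branched-chain amino acid and fatty acid oxidation genes to the left, with medians of -0.17 and -0.16.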

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

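Several tests in this part were chosen after the results were seen. These covered an extra copy of chromosome 7, fast-fibre genes with and without Myl1, and a DNA difference on chromosome 7. They also covered a lower cardiomyocyte share, more fibroblasts and the time of day. The others were set before, but those about chromosome 7 concern a chromosome picked after the data were seen.

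Single samples stood apart from the 5 others of their group, by the gap to the nearest sample divided by the group's range, in 26 of 350 groups of values examined, where chance gives about 17.5. Vps13c-cKO replicate 6 had 7 of these, more than any other library: it was high for Ndnf (ratio 0.649), Ano10 (0.644), Hmgcs1 (0.692), Manf (0.627) and Hspa5 (0.649), and low for Ankrd1 (0.635) and for Ccn2 (0.893), at 65.5 CPM against 90.1 to 93.1 CPM in the other 5. The other knockout libraries that stood apart were replicate 1 for Scd1 (0.687), replicate 2 for Dnajb9 (0.682), replicate 3 for Aldh1a2 (0.692), replicate 4 for mt-Atp6 (0.786), and replicate 5 for Fasn (0.629), Cox6a2 (0.680) and Irf7 (0.724). Among WT libraries they were replicate 2 for Pdp2 (0.651), replicate 3 for Acadsb (0.723) and Dbt (0.638), replicate 4 for Acta1 (0.708), Hspb7 (0.750) and Irf7 (0.724), replicate 5 for Plin2 (0.699) and Pcyt2 (0.650), and replicate 6 for Cyp2b10 (0.638), Echs1 (0.690), Atp6v1d (0.648) and mt-Atp6 (0.704). Without Vps13c-cKO replicate 6, 650 genes were higher and 617 lower.

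The concentration of changed genes on chromosome 7 was weighed first. An extra copy predicts a shift near 0.58 on the log2 scale, and the median of chromosome 7 genes differed from that of the others by 0.00302, which argues against it. Skeletal muscle carried over with the hearts would bring its abundant transcripts alike: 7 fast-fibre genes off chromosome 7 gained -0.135 ± 0.196 (SE) of the CPM gain of Mylpf, Tnni2 and Tnnt3, and without Myl1, which WT heart expresses, 0.00504 ± 0.00443, which argues against carry-over. Of the 40 tested genes nearest to Vps13c, 7.50% changed (exact 95% interval 1.57% to 20.4%), but they lie on chromosome 9, so passenger DNA around the targeted gene would not place changes on chromosome 7 and this test decides nothing about them. A DNA difference on chromosome 7 between the groups, such as an inserted transgene or a passenger segment, cannot be told apart from an effect of the knockout, since no group separates them. The odds ratio of 2.39 for changed genes in the last 478 genes by order against the first 477 (Fisher's exact p = 4.76e-07) could not have gone against it and decides nothing. Of 100 splits of the 12 samples, 2 gave an odds ratio as high on chromosome 7 among their 1331 genes of smallest p, the real split (2.03) and a highest other of 2.16, which exchanged 1 WT mouse for 1 Vps13c-cKO mouse. Chance is thus unlikely but not excluded, since the splits scored chromosome 7 alone, which was picked after the data were seen.

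The rise of fibroblast and matrix genes was weighed second. A lower share of cardiomyocytes would raise the markers of every other cell type alike. The fibroblast median lay 0.31 (0.315) above the endothelial median of -0.08 on the log2 scale (permutation p = 1e-05 over markers). That is the smallest p that 100000 resamples can give, and it treats markers, not mice, as independent. Medians were also below 0 for smooth muscle cells and adipocytes (-0.11 and -0.21). They were above 0 for macrophages, Schwann cells and neurons, mesothelial cells, red blood cells, lymphocytes and neutrophils (0.13 to 0.30). The adipocyte median rests on 5 tested genes, among them Lpl, which heart muscle expresses, so it does not bear on this question. The fibroblast and endothelial values argue against a lower cardiomyocyte share as the only cause, but do not exclude a part in the rise. Fibroblast markers that are not on the matrix list had a median of 0.209, but this restates the rise of the list they come from and decides nothing. More fibroblasts and more of these transcripts per fibroblast both stay open.

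The difference in clock genes was weighed last. Genes that peak with Bmal1 (Arntl, Clock, Npas2, Nfil3 and Cry1) had a median log2 fold change of -0.42 and genes of the opposite phase 0.19, a difference of -0.607 (two-sided exact permutation p = 0.00481 over genes). Of the 5 genes of the first set 3 were lower; of the 11 of the second 2 were higher (Per2 and Ciart), 1 was lower (Nr1d1) and 8 did not pass. The medians are consistent with a different time of day at collection, though few of the second set rose; Nr1d1 and Per2 lost their calls with robust empirical Bayes (adjusted p = 0.0768 and 0.0882). A change of the clock by the knockout predicts much the same and stays open, as no collection time is given in the sources used here. Arntl and Dbp lie on chromosome 7, where changed genes were concentrated, and the medians were not compared without them.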

How the results depend on the processing

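Leaving out chromosome 7 genes and the chromosome 7 odds ratios were added after the results were seen; the other settings were planned. The Vps13c change kept its direction and call in every setting run (log2 -1.80 to -1.74 with one sample left out). Genes higher numbered 561 to 725 and genes lower 504 to 672 with one sample left out, and 608 to 784 and 546 to 699 otherwise, all within 1.5 times of the 700 and 631; 0 shared calls changed sign, and scaling moved the median gene by at most 0.01. Genes changed at least 2-fold numbered 76 to 93 with one sample left out, but 229 without a filter (more weak genes tested). They numbered 18 at a minimum mean of 5 CPM (fewer tested). Without chromosome 7 genes, which held 29 of the 79 in the main test, they numbered 50. By DESeq2 they numbered 157. DESeq2 was run without the filter filterByExpr, so it too took in more weak genes, and the effect of the method itself was not tested. Lists higher and lower numbered 12 to 15 and 6 to 8 with one sample left out, and 12 and 7 by fry. Without chromosome 7 genes they numbered 11 and 6, where skeletal muscle and adipocytes had too few genes left to be tested. With an estimated correlation they numbered 5 and 1 (the cause was not tested). DESeq2, unweighted limma-voom and robust empirical Bayes were not run for lists. The replicate numbers do not pair the samples: same-numbered samples correlated by -0.04 to 0.06, and 1 of 6 correlated best with its own number. With the replicate block, 687 genes were higher, 625 lower (1203 of 1312 calls shared), 80 changed at least 2-fold, and 14 and 7 lists passed. Of 3732 comparisons over 171 named genes, 3617 kept their side of the threshold, 77 lost it (61 with one sample left out), 38 gained it and 0 reversed; Hspa5, Gramd1b, Myh11 and Cidea lost it in 2 settings that kept all samples. The chromosome 7 odds ratio ran from 1.92 to 2.34. Among 100 of 462 splits of the samples, the real one gave 1331 genes and the highest other 71. It gave 23 lists, against 21 in the highest other and a median of 9 over the others. The split with 21 lists exchanged 1 WT mouse for 1 Vps13c-cKO mouse, so it kept most of the real contrast. The 7 splits of that kind gave a median of 16 lists. Splits with 3 mice of each group on either side gave at most 11. Only the real split was as large for each count. This argues against chance for the count of genes. For the count of lists it makes chance unlikely but does not exclude it. The margin for lists is narrow: of the 23 lists, 9 had as small a p in under 5 splits, namely cardiac stress, calcium handling, fatty acid oxidation, fatty acid synthesis, matrix, branched-chain amino acids, p53 targets, fibroblasts and skeletal muscle. Of the smallest simulated changes, 70.2% were recovered; whether depth, the spread between mice or their number limits this was not tested.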

Other observations

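The tests of level on chromosome 7, of highly and of weakly expressed genes, were chosen after the results were seen. Interferon-stimulated genes were higher for 6 of 46 and lower for 0 (7 and 0 adjusted over the list alone; list adjusted p = 0.0126, and adjusted p = 0.434 with an estimated correlation; past the threshold in 18 of 19 settings), with Ifit3 at 8.42 ± 1.45 CPM in WT and 14.1 ± 1.01 CPM in Vps13c-cKO (SD, n = 6 each), and Ifit2, Ifit3b and Irf7 at log2 fold changes of 0.54 ± 0.09 (SE), 0.72 ± 0.17 and 0.45 ± 0.11. Inflammatory cytokine and adhesion genes were higher or lower for 0 of 18 (0 adjusted over the list alone; list adjusted p = 0.0777, and higher by fry with adjusted p = 0.0117). Cell cycle genes were higher for 3 of 33, the cyclin D genes Ccnd1 and Ccnd2 and the replication licensing gene Mcm2, and lower for 0 (3 and 0 adjusted over the list alone; adjusted p = 0.0184, 0.434 with an estimated correlation and 0.112 without chromosome 7 genes; past the threshold in 18 of 19 settings). Ccnd2 lost its call with robust empirical Bayes (adjusted p = 0.0882). Among immediate early genes, Egr3 rose by 1.49 ± 0.32 (SE) and Myc by 0.53 ± 0.13, while Nr4a3 fell (2 higher and 1 lower of 19; 3 and 1 adjusted over the list alone; adjusted p = 0.728). Clock genes were higher for 2 of 19 and lower for 4 (6 and 5 adjusted over the list alone; adjusted p = 0.50).

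Of the remaining cell type lists, adipocyte markers were higher for 1 of 5 (Cidea) and lower for 2 (Lpl and Aqp7), with 1 and 3 adjusted over the list alone (adjusted p = 0.0365, and adjusted p = 0.217 with an estimated correlation). The adipocyte list passed in 11 of 19 settings, and Cidea lost its call in 8 of 12 cases with a sample left out; heart muscle expresses Lpl at 7976 CPM. Schwann cell and neuron markers were higher for 1 of 9, Uchl1, and mesothelial markers higher for 2 of 5 (Aldh1a2 and C3) and lower for 1 (Efemp1), with adjusted p = 0.268 and 0.698 and the same counts adjusted over the list alone. Aldh1a2 lost its call in 7 of 12 cases with a sample left out, and C3 with robust empirical Bayes. Red blood cell genes passed for 0 of 7 (0 adjusted over the list alone; adjusted p = 0.868), with a median and mean above 0 and a test direction below it. Only 2 lymphocyte genes and 1 neutrophil gene were tested, and 0 of them passed.

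On chromosome 7 level and direction went together. Among tested genes at 43.7 CPM or more in WT, 54 of 191 on chromosome 7 fell (28.3%), against 10.6% elsewhere, an odds ratio of 3.31 (95% interval 2.32 to 4.67; two-sided Fisher's exact p = 1.11e-10). Among tested genes at 5.65 CPM or less in WT, 52 of 324 rose (16.0%), against 4.52% elsewhere. The odds ratio was 4.04 (95% interval 2.796 to 5.77, Fisher's exact p = 4.48e-13). A gene near the floor in WT could pass the filter through Vps13c-cKO alone, and could hardly be called lower. The rises in this set therefore do not decide between a one-way shift and more change in either direction. The opposite directions were not set apart from other chromosomes: 3.66% of the first set rose, against 7.23% elsewhere (Fisher's exact p = 0.0770), and 0 of the second fell, against 0.940% (Fisher's exact p = 0.103). Genes in between changed more often in both directions, with 7.05% lower against 3.67% (Fisher's exact p = 0.00124) and 7.50% higher against 4.72% (Fisher's exact p = 0.0155). Active genes lower and near-silent genes higher on one chromosome is a hypothesis of a loss of contrast between them there, which may come from the DNA or chromatin of that chromosome in the knockout mice. These tests do not say which; DNA sequence and chromatin accessibility along chromosome 7 in both groups would bear on it and were not used here.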
